A study of Homo sapiens with 3 samples.

How the data were processed

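Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in U2OS, a human osteosarcoma cell line, with an antibody against Spindlin1, with an antibody against C11orf84, and without antibody (Input). Each of the 3 samples was 1 library. Per the labels' protocols, untreated cells were fixed with 1% formaldehyde for 10 min, fixation was stopped for 5 min by adding glycine to 0.125 M, and libraries were made by Illumina protocols. A peak list was used for Spindlin1 and for C11orf84. No file of the Input sample was used here.

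Reads were aligned with Bowtie 1.2.2 to the human genome build hg19, per the submitters' processing notes. The peak caller, its threshold and the control it used are not given in the sources used here. Each list was taken as made from its own library, since each belongs to a single sample. The deposited start, end and summit coordinates of each peak were read as hg19 positions and are printed counting from 1. The deposited fold enrichment of a peak, made by the authors, is the ratio of its summit to a local background. The authors' lists also give a −log10 p-value and a −log10 q-value of the summit. The score in the deposited lists was the whole part of 10 times the −log10 q-value in 100% of peaks and was not used further. These values are the authors' own. They served to describe, rank and filter peaks within their own list and to recover summit depth and background, and folds of the 2 lists printed for the same region are each relative to their own list.

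Summit depth was recovered from the deposited values. With k fragments over the summit and a background of λ fragments, the fold was taken as (k + 1)/(λ + 1) and the p-value as the Poisson probability of more than k fragments. A whole number k met both deposited values of every peak (100% of 153468 Spindlin1 and 177639 C11orf84 peaks, chromosome Y included), with a largest error of 0.000174 and 0.000148 in −log10 p. For 16 Spindlin1 peaks and 0 C11orf84 peaks the next best whole number came within 0.001. The lowest background, called the floor, was 0.949 fragments for Spindlin1 and 1.04 for C11orf84, and 48.1% and 49.3% of peaks stood at it within 0.1%. Every other background was a whole multiple of a fitted unit, scaled to a window of 1 fragment length (26.5% and 27.4% of peaks), 1 kb (13.6% and 12.7%) or 10 kb (11.7% and 10.7%). That unit was taken as an Input read here and below, which is an inference, since the control is not given. A single Input read in a fragment-length window was worth 0.541 fragments in the Spindlin1 list and 0.566 in the C11orf84 list. A background of at least 2 times the floor is called raised. Total read numbers are unknown, but the worth of an Input read put the depth of the C11orf84 library at 1.04 times that of the Spindlin1 library, and the floors with the shortest peaks (172 and 180 bp) gave 1.04 as well.

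Comparisons used chromosomes 1 to 22 and X, and the peaks on chromosome Y were left out of them. Intervals that overlap within a list were to be merged, and 0 were found. A peak counted as shared when it had at least 1 bp in common with a peak of the other list. Chance was taken from 100 random placements of the same intervals on the same chromosome, anywhere between the first and the last peak outside peak-free stretches of 1 Mb or more (2663 Mb open to placement). Another 100 placements moved each interval by at most 500 kb either way, which roughly keeps the regional density of peaks, and was also done by group of fold and of summit depth after the data were seen. These shifts were bounded only at the chromosome start, so intervals could land past the last peak or in peak-free stretches. Shares carry exact Clopper-Pearson 95% intervals, which give counting error only and take each peak as independent. Neighbouring peaks are not independent, so these intervals are likely too narrow. With 1 library per antibody there is no replicate check, and no p-value is given. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. On simulated data the recovery returned the exact summit depth of 100% of 17274 peaks, the planted status of all 10000 intervals, overlapping or not, was returned, and random placement gave 50.2% where 49.9% was due.

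The overlap in each direction, the peak numbers, the overlap by 10 equal groups of fold, and their alternatives (overlap of at least 50% of both intervals, −log10 q of at least 10, the 10000 peaks of highest −log10 q, summits at most 200 bp apart, no merging, and shifts of at most 500 kb) were chosen before the data were examined. The rule for single regions, also set then, took the 10 peaks of highest fold and the 8 of highest fold without a peak of the other list within 5 kb at gene promoters. It was carried over to all peaks by coordinates, with ties ordered by −log10 q and then position, and the text names the leading ones. Chosen after the data were seen were the recovery of summit depth and background, the counts along chromosomes and in windows of 1 Mb, the outermost 5 Mb of chromosome arms, peaks of at least 2 kb, and the 20 peaks of highest −log10 q. Arm ends were counted from the outermost peak of either list, without the short arms of chromosomes 13, 14, 15, 21 and 22, which leaves 41 ends.

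Peaks were not assigned to genes. The only gene table used here is of GRCh38.p14, and 8229 peaks lie beyond the last gene of their chromosome in that table, so its positions cannot be set against hg19 intervals. Promoter shares, gene-level overlap, lists of genes, gene classes and ribosomal DNA contigs were planned and are not analysed here. The lists used here hold no peaks on unplaced contigs.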

Results

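Spindlin1 is a chromatin protein that reads methylated tails of histone H3, and C11orf84 is a protein known to bind it. The series asked where in the genome each of them lies. ChIP-seq libraries of the 2 proteins were made in U2OS cells, 1 library each, beside an Input library without antibody, and the peaks called in each library were compared by position in hg19. There are no replicates, so none of the intervals below covers variation between experiments. They give counting error with each peak taken as independent. Neighbouring peaks are not, so the intervals are likely too narrow.

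On chromosomes 1 to 22 and X the Spindlin1 list held 153378 peaks that covered 46.6 Mb. The C11orf84 list held 177557 peaks over 60.0 Mb. These are 1.75% and 2.25% of the 2663 Mb in which peaks could be placed. Peaks were narrow in both lists, with a median width of 229 bp for Spindlin1 (interquartile range 184 to 345 bp) and 248 bp for C11orf84 (195 to 380 bp). The authors' fold enrichment had a median of 5.72 in the Spindlin1 list (range 2.0 to 22.1) and 5.89 in the C11orf84 list (range 1.87 to 19.9).

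Most peaks of both proteins rested on few fragments. The summit depth recovered from the deposited values had a median of 11 fragments for Spindlin1 (interquartile range 10 to 14) and 12 for C11orf84 (10 to 15), and 95.6% and 93.9% of peaks had fewer than 20. The lowest −log10 q was 2.05 and 2.01, and the medians were 6.61 and 6.46. A −log10 q of at least 10 was reached by 18068 Spindlin1 peaks and 27877 C11orf84 peaks. By the recovered values, depth of the C11orf84 library was 1.04 times that of the Spindlin1 library, so the numbers of peaks are not measured at equal depth.

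The 2 peak lists coincided at many regions, to an extent that depended on how much overlap was asked for. Of the Spindlin1 peaks, 106909 (69.7%, 95% interval 69.5 to 69.9) overlapped a C11orf84 peak. Of the C11orf84 peaks, 102285 (57.6%, 57.4 to 57.8) overlapped a Spindlin1 peak. With at least 50% of both intervals covered, the shares were 47.5% and 41.1%, and with summits at most 200 bp apart they were 55.1% and 47.5%. In bases, 30.7 Mb were common to both lists, which is 65.9% of the Spindlin1 territory and 51.2% of the C11orf84 territory. Summits of shared Spindlin1 peaks lay at a median of 58 bp from the nearest C11orf84 summit, and 54 bp the other way, a distance that overlap itself keeps short in peaks of these widths (medians of 264 and 312 bp).

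Random placement on the same chromosome gave an overlap of 5.54% on average and at most 5.66% for Spindlin1, and 4.71% and at most 4.81% for C11orf84. Shifts of at most 500 kb, which keep the peaks in their own regions, gave 17.0% (at most 17.3%) and 14.2% (at most 14.3%). The observed shares lay above the highest of the 100 placements in both directions and under both kinds of placement. When both lists were reduced to their 10000 peaks of highest −log10 q, 35.5% of Spindlin1 and 34.1% of C11orf84 peaks overlapped, against 10.3% and 9.91% after local shifts, and with a −log10 q of at least 10 in both lists the C11orf84 share was 30.9% against 8.32%. The series has 1 Input library for both lists, so part of the excess over chance may come from that library.

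The peaks of highest −log10 q in each list nearly all overlapped a peak of the other list. Among the 10000 Spindlin1 peaks of highest −log10 q, 93.3% (92.8 to 93.8) overlapped some C11orf84 peak, and 91.1% (90.5 to 91.6) of the top 10000 C11orf84 peaks overlapped some Spindlin1 peak. Local shifts of these peaks gave 29.5% and 28.9%, more than for the whole lists. Each list was also divided into 10 equal groups by the authors' fold, and the shared part of the Spindlin1 list went from 58.3% (57.6 to 59.1) in group 1, the lowest, to 90.6% (90.1 to 91.0) in group 10. In the C11orf84 list it went from 43.7% (43.0 to 44.4) to 85.3% (84.8 to 85.9). Neither rise was strictly step by step. Group 2 of Spindlin1 stood at 57.8%, and C11orf84 fell from 45.3% in group 2 to 44.4% in group 3 and from 54.4% in group 5 to 53.9% in group 6. Chance overlap after local shifts rose as well, from 12.8% in group 1 to 28.0% in group 10 for Spindlin1 and from 10.4% to 25.9% for C11orf84.

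The same relation held in summit depth among peaks at the background floor, where all peaks of a list were set against 1 background. Spindlin1 peaks of 7 fragments overlapped C11orf84 in 50.04% (48.2 to 51.9), those of 10 fragments in 63.1%, those of 15 in 86.9% and those of 20 in 98.0% (95.4 to 99.3). For C11orf84 the shares were 31.1% (29.3 to 33.0), 44.4%, 76.4% and 90.9% (87.8 to 93.4). At 25 or more fragments, 39 of 40 Spindlin1 peaks and 123 of 124 C11orf84 peaks were shared. After local shifts, the overlap went from 12.9% at 7 fragments through 41.5% at 20 to 60.7% at 25 or more for Spindlin1, and from 9.41% through 34.4% to 56.2% for C11orf84.

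**Figure D1:**
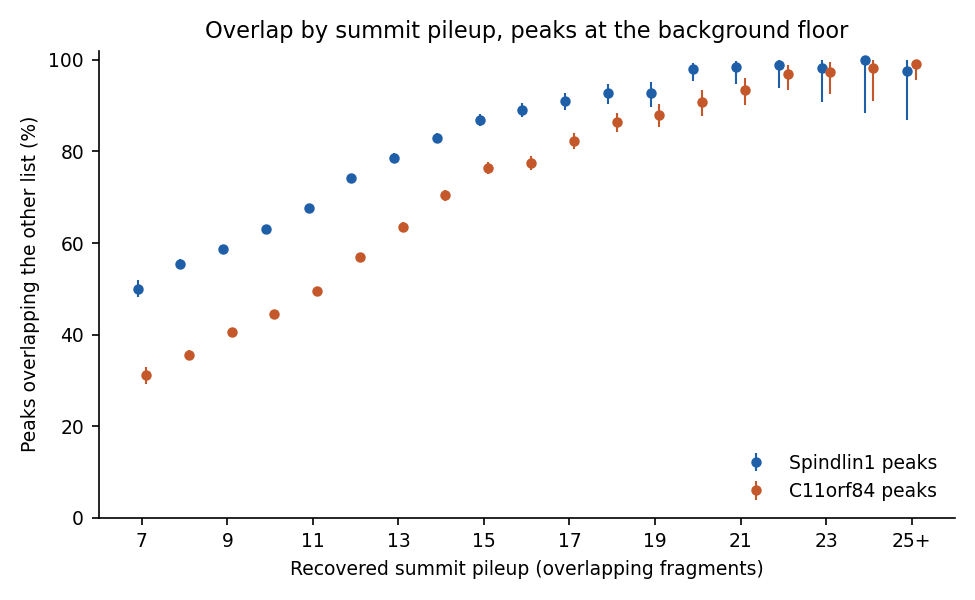
Share of peaks (%, vertical axis) that overlapped the other list, by the recovered number of fragments over the summit (horizontal axis; the last point holds 25 or more), for Spindlin1 (blue) and C11orf84 (orange) peaks at the background floor. Points are shares and bars exact 95% intervals; the share went from 50.04% at 7 fragments to 98.0% at 20 for Spindlin1 and from 31.1% to 90.9% for C11orf84.

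The regions of highest fold were the same in both lists at 3 places. A region of chromosome 8 (58118316 to 58118807) had the highest fold of the Spindlin1 list, 22.1 at 45 fragments, and the C11orf84 peak there (58118304 to 58118812) had a fold of 16.3 at 43 fragments. Chromosome 1 (156186163 to 156186724) held the highest fold of the C11orf84 list, 19.9 at 154 fragments, and the Spindlin1 peak there had a fold of 20.1 at 150 fragments. On chromosome 20 (26189792 to 26190381) the fold was 20.0 for Spindlin1 and 17.8 for C11orf84. The background at the chromosome 1 region was raised, at 6.85 times the floor for Spindlin1 and 6.54 times for C11orf84, and at the chromosome 20 region it was 3.42 and 3.27 times. At the chromosome 8 region it was 1.14 and 1.64 times. These regions are also among the 20 of highest −log10 q in both lists. At those on raised background, reads of repeats collapsed in the assembly cannot be told apart from binding.

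The end of the long arm of chromosome 8 supplied most of the other leading peaks. Spindlin1 peaks at 144958424 to 144962505 and at 145813261 to 145816768 both had a fold of 15.4 at 29 fragments over the floor. The C11orf84 peak at 145094067 to 145095772 had a fold of 17.7 at 35 fragments. Outside chromosome 8, C11orf84 had a fold of 16.7 on chromosome 16 (89695635 to 89696343) and 15.7 on chromosome 9 (139365970 to 139366622), and Spindlin1 had 14.9 on chromosome 20 (61978474 to 61981966). All 10 peaks of highest fold in each list overlapped a peak of the other.

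Peaks found in 1 list alone were numerous and weaker. In all, 46469 Spindlin1 peaks and 75272 C11orf84 peaks had no overlap with the other list, and 12826 (8.36%) and 19332 (10.9%) had no peak of the other within 5 kb. Spindlin1 peaks without overlap had a median fold of 5.46 at 10 fragments, against 6.14 at 12 fragments for shared ones. For C11orf84 these were 5.40 at 11 fragments and 6.10 at 13. Unshared peaks were also narrower, with medians of 191 against 264 bp and 208 against 312 bp.

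Among the peaks farther than 5 kb from any peak of the other list, the highest Spindlin1 fold was 10.97 on chromosome 2 (100012974 to 100013204, 21 fragments), which ranked 758 in its list. The next were chromosome 3 (95894442 to 95894687, fold 10.9) and chromosome 15 (64269384 to 64269611, fold 10.6). For C11orf84 the highest was chromosome 6 (65010050 to 65010300, fold 12.7, 26 fragments), at rank 222, followed by chromosome 1 (175122635 to 175122945) and chromosome 19 (267030 to 267643), both at 11.3. A missing peak in the other list is the absence of a call at its depth and does not measure absence of the protein.

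Peak density differed widely between chromosomes and did so alike for the 2 proteins. Chromosome 22 was the densest, with 245 Spindlin1 and 276 C11orf84 peaks per Mb, followed by chromosome 17 (138 and 156), chromosome 19 (112 and 149.9), chromosome 16 (103 and 116) and chromosome 20 (99.8 and 110.1). Chromosomes 17, 19 and 22 are known to be rich in genes. The lowest densities were on chromosome X (5.04 and 6.90 per Mb), chromosome 13 (17.9 and 22.8) and chromosome 4 (19.8 and 24.5), against a mean of 52.1 and 60.4 per Mb. The shared part of the Spindlin1 list ranged from 53.5% on chromosome 21 to 78.2% on chromosome 22.

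At a finer scale, peaks of both proteins lay in dense clusters. The densest 5% of the 2805 windows of 1 Mb that held a peak (141 windows) contained 36.5% of Spindlin1 and 35.0% of C11orf84 peaks, whereas the median window had 17 and 18. The densest of all was on chromosome 17 at 79 to 80 Mb, with 831 Spindlin1 and 785 C11orf84 peaks, followed by chromosome 20 at 61 to 62 Mb (816 and 747), chromosome 16 at 1 to 2 Mb (770 and 784), chromosome 7 at 1 to 2 Mb (817 and 735) and chromosome 5 at 1 to 2 Mb (726 and 731). Across windows the numbers of the 2 lists had a Pearson correlation of 0.989 and a Spearman correlation of 0.971. Windows are not independent replicates, so no p-value is given.

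Many of the dense windows lay at the ends of chromosome arms. The outermost 5 Mb of the 41 arm ends held 43043 Spindlin1 peaks (28.1%, 27.8 to 28.3) and 49564 C11orf84 peaks (27.9%, 27.7 to 28.1) in 7.70% of the length, 3.65 and 3.63 times their part. The fullest for Spindlin1 were the long arm ends of chromosomes 17 (3232 Spindlin1 and 3311 C11orf84 peaks), 9 (2887 and 3145) and 8 (2890 and 2653) and the short arm ends of chromosomes 7 (2711 and 2662) and 16 (2675 and 2875). Others were nearly empty, such as the short arm ends of chromosomes X (2 and 1), 10 (10 and 26) and 9 (33 and 45). The density was above the genome mean at 31 ends for Spindlin1 and at 32 for C11orf84. That mean is over the 2942 Mb from the first to the last peak of each chromosome, peak-free stretches included. The percentage of length sets whole ends against the 2663 Mb open to placement. The multiples and the mean therefore do not rest on the same total.

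The excess at the ends was greater closer to the tip. The outermost 2 Mb held 14.3% and 13.9% of peaks in 3.08% of the 2663 Mb open to placement, 4.64 and 4.53 times their part. The outermost 10 Mb held 38.8% and 39.0% in 15.4% of that length, 2.52 and 2.53 times. In the outermost 5 Mb, 76.9% (76.5 to 77.3) of Spindlin1 peaks were shared, against 33.6% after local shifts, and 66.9% (66.6 to 67.2) were shared elsewhere, against 10.5%. For C11orf84 these shares were 62.5% against 27.7% at the ends and 55.7% against 8.95% elsewhere. Shifts could carry intervals near a tip past the outermost peak, which can lower the chance shares at the ends. Ends were chosen for this count after the density along the genome had been seen.

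**Figure D2:**
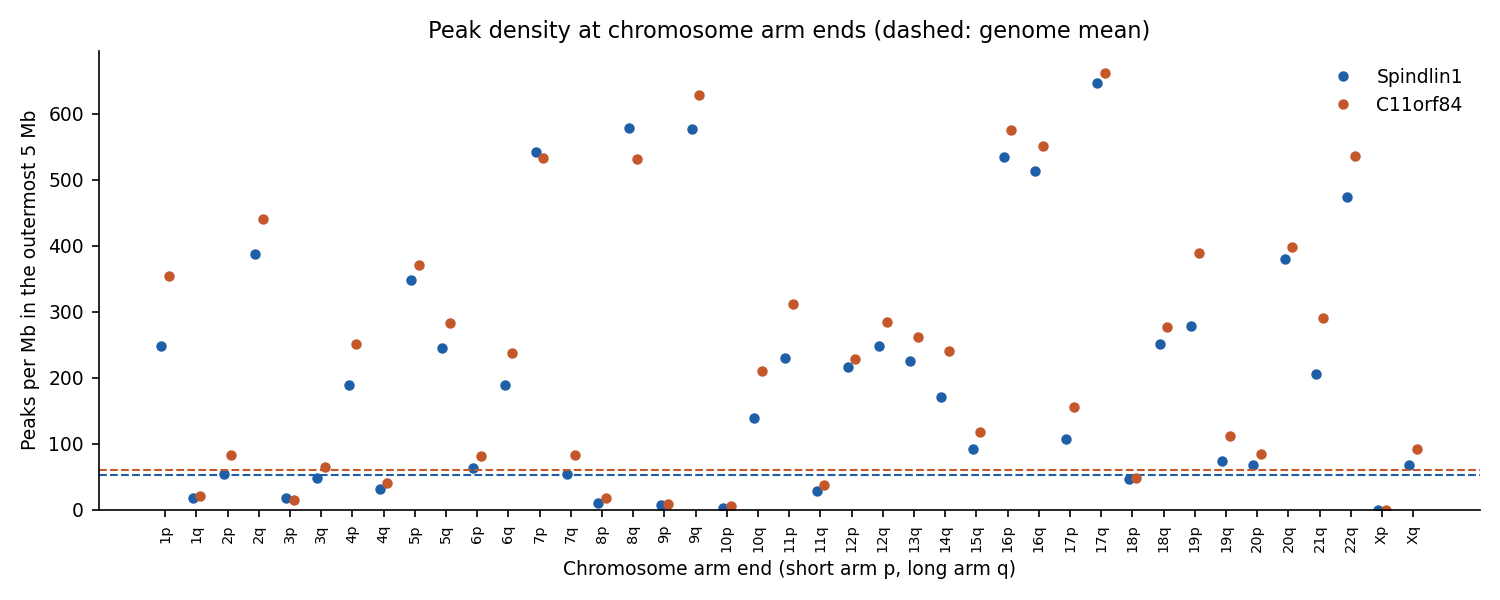
Peaks per Mb (vertical axis) in the outermost 5 Mb of each of 41 chromosome arm ends (horizontal axis; p short arm, q long arm), as 1 point per list, Spindlin1 in blue and C11orf84 in orange, with dashed lines at the genome means of 52.1 and 60.4. The long arm of chromosome 17 was highest at 646 and 662 per Mb, and 31 Spindlin1 and 32 C11orf84 points lay above their mean.

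Wide peaks were concentrated near the end of the long arm of chromosome 8. Peaks of at least 2 kb numbered 270 for Spindlin1 and 553 for C11orf84, and every one overlapped the other list. Chance overlap was not computed for them. It would be high, since they are wide and 84.8% and 80.1% of them lay in the dense outermost 5 Mb of arms. Chromosome 8 held 126 of the Spindlin1 ones (46.7%, 40.6 to 52.8) and 187 of the C11orf84 ones (33.8%, 29.9 to 37.9), against 4.90% and 4.32% of all peaks, and 124 and 181 of them lay past 140 Mb. Chromosomes 7 (35 and 75), 9 (34 and 68) and 20 (25 and 51) came next. The widest Spindlin1 peak was on chromosome 8 (145615352 to 145622576, 7225 bp) and the widest C11orf84 peak on chromosome 9 (139742393 to 139754713, 12321 bp, background 4.91 times the floor). Width also depends on depth and background, and 60 and 100 of the wide peaks stood on a raised background. Below that cut, the outermost 5 Mb of the long arm of chromosome 8 had a median background of 1.47 times the floor in both lists. Over the whole lists the median was 1.05 and 1.01 times. Median summit depth in that end was 17.5 and 20 fragments, against 11 and 12 over the whole lists. Whether extra DNA copies there contributed to the wide peaks was not tested.

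In the window at 142 to 143 Mb of chromosome 8, with 724 Spindlin1 and 671 C11orf84 peaks, the median background was 1.67 and 1.63 times the floor and the median summit depth 18 and 20 fragments. Another stretch of chromosome 8 had a higher background with fewer peaks, reaching 3.99 and 3.87 times the floor at 29 to 30 Mb, where 112 Spindlin1 and 100 C11orf84 peaks were found.

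**Figure D3:**
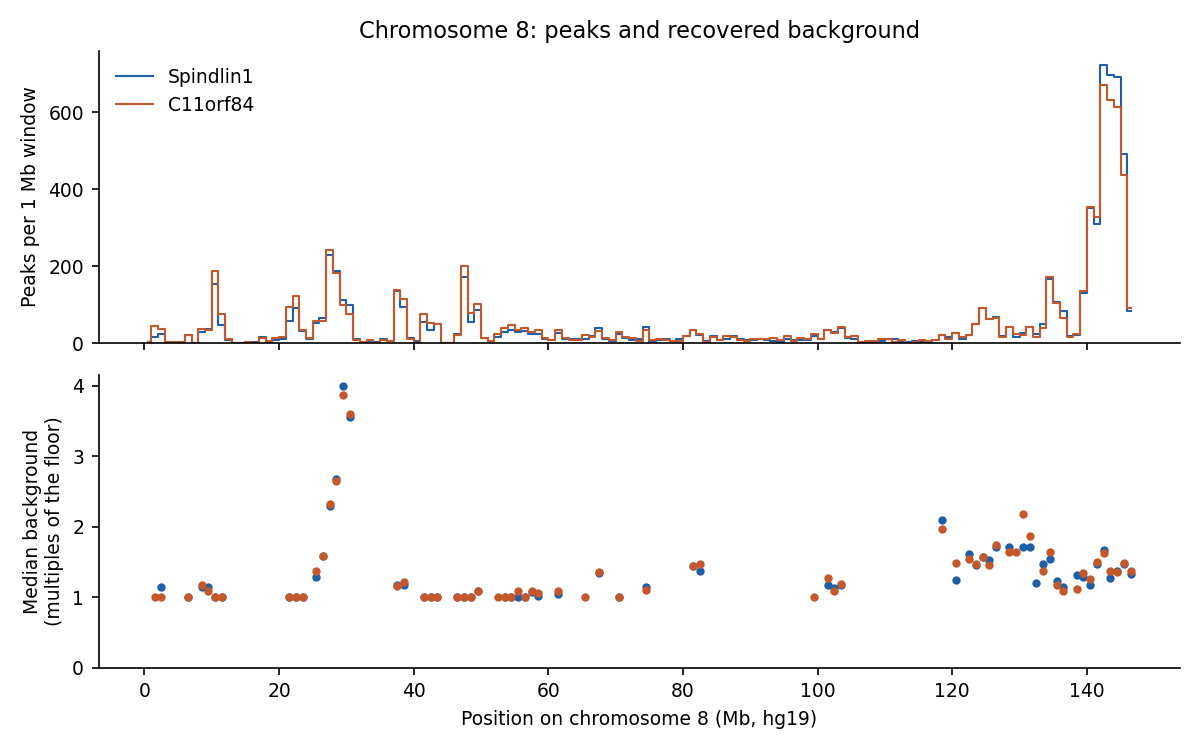
Chromosome 8 in hg19 (horizontal axis, Mb), with the number of peaks per 1 Mb window above and the median recovered background of those peaks below, in multiples of the floor and for windows of at least 20 peaks (Spindlin1 blue, C11orf84 orange). Peak numbers were highest at 142 to 143 Mb (724 and 671), whereas background was highest at 29 to 30 Mb (3.99 and 3.87 times the floor).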

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

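The tests on summit depth, on background at arm ends and on the peaks of highest −log10 q were chosen only after those results were seen, and the test against local peak density was set before its own result was seen but after background had been recovered.

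Chromosome Y, which entered no comparison, carried 90 Spindlin1 peaks and 82 C11orf84 peaks, and they are listed because the report left them out. These calls are not read as binding on chromosome Y, which was not tested. Their median background was 3.19 times the floor for Spindlin1 and 3.27 times for C11orf84. A raised background was found at 62 of the Spindlin1 peaks (68.9%) and 53 of the C11orf84 peaks (64.6%), against 9.07% and 9.19% on the other chromosomes. Median summit depth was 20 and 20.5 fragments.

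The shared part of both lists rose with summit depth. Peaks found in 1 list alone had a median of 10 fragments for Spindlin1 and 11 for C11orf84, against 12 and 13 for shared ones. Crowding of peaks on the scale of the shifts (at most 500 kb) is argued against as the only source of the overlap. The overlap of Spindlin1 peaks at the floor exceeded the highest of 100 shifted placements by 49.6 percentage points. Closer clusters are broken up by such shifts, so crowding on a finer scale stays open. Part of the rise could follow crowding, since the overlap after such shifts rose too, from 12.9% at 7 fragments to 41.5% at 20. A detection limit, by which 1 library misses shallow regions that both proteins occupy, cannot be told apart from regions bound by 1 protein that happen to be shallow, since the 2.5% of Spindlin1 peaks left unshared at 25 or more fragments would be as low under either. Signal that any antibody would recover stays open too, as no unrelated antibody was analysed here, and no biological explanation was tested.

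Peaks of both proteins were concentrated at chromosome arm ends. Peaks at the floor were more frequent at the ends than elsewhere, by 14.5 percentage points in the list with the smaller difference, although the long arm of chromosome 8 and the short arms of chromosomes 12 and 18 had median backgrounds of 1.47, 1.46 and 2.03 times the floor in the Spindlin1 list. Extra DNA copies and Input coverage lowered by base composition cannot be told apart, because 58.6% of end peaks in the list with fewer of them stood at the floor. Input coverage below the floor cannot be read, and a lower coverage could hide extra copies. Density of genes near the ends remains a possible explanation that was not tested.

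The peaks of highest −log10 q lay largely on raised background, at 19 of the leading 20 for Spindlin1 and 16 of 20 for C11orf84, and all of them overlapped the other list. Several stand beside centromeres, such as chromosome 1 (121484114 to 121485459, 279 Spindlin1 fragments on 109.6 times the floor) and chromosome 6 (58776147 to 58779343, 274 fragments on 81.0 times). At chromosome 8 (58118316 to 58118807), the exception in the Spindlin1 list, the background was 1.14 times the floor, and 1.64 times in the C11orf84 list. Reads of repeats collapsed in the assembly and binding at repeats cannot be told apart, since a raised background is what was seen first and no value separates them.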

How the results depend on the processing

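The alternatives on background and on chromosome arm ends, and all results on arm ends and wide peaks, were chosen after the data had been seen, and the others were planned. Overlap was 69.7% for Spindlin1 and 57.6% for C11orf84 in the report. It became 47.5% and 41.1% when at least 50% of both intervals had to be covered, 55.1% and 47.5% for summits at most 200 bp apart, 49.0% and 30.9% with a −log10 q of at least 10 in both lists, and 35.5% and 34.1% for the 10000 peaks of highest −log10 q. Without peaks on raised background it was 66.2% and 55.0%, and without the outermost 5 Mb of arms 66.9% and 55.7%. The first 2 ask for more of each pair and the next 2 take partners away by construction. Leaving out raised background in both lists also takes partners away, and it drops peaks that were shared in 79.1% and 68.8% of cases. Leaving out the ends drops peaks that were shared in 76.9% and 62.5% of cases. The overlap expected by chance was 17.0% and 14.2% with shifts of at most 500 kb, against 5.54% and 4.71% on the whole chromosome, and it stayed below every observed share.

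Arm ends held 28.1% of Spindlin1 and 27.9% of C11orf84 peaks at 5 Mb, 14.3% and 13.9% at 2 Mb, and 38.8% and 39.0% at 10 Mb, which follows from the length taken. The share was 36.2% and 33.5% among peaks with a −log10 q of at least 10, and 28.9% and 28.8% without raised background, and the cause was not tested. A −log10 q of at least 10 left 18068 and 27877 peaks of 153378 and 177557. Counting without merging could change nothing, since no intervals overlapped within a list. Wide peaks numbered 210 of 270 and 453 of 553 without raised background. In all, 24 alternative values moved beyond the counting interval or by more than 1.5 times, and 4 did not. Both counts hold values fixed by construction, such as other lengths of arm end and counting without merging, so they do not measure robustness. Promoter windows, gene-level overlap, lists of genes and ribosomal DNA were not run, since no hg19 annotation and no contigs were used here. No replicate could be left out, and no paired analysis was possible because each antibody has 1 library. Fewer than 20 fragments lay over the summit of 95.6% of Spindlin1 and 93.9% of C11orf84 peaks, and at this depth a missing overlap does not show that the other protein was absent.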

Other observations

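The windows, chromosomes and regions below were chosen after the data had been seen, and the test of a common Input was set before its own result was seen but after background had been recovered.

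The balance between the 2 lists varied little along the genome. Spindlin1 supplied 46.3% of all peaks, and in the middle 50% of the 777 windows with at least 100 peaks its part lay between 43.7% and 48.1%. The windows richest in C11orf84 were on chromosome 10 at 132 to 133 Mb (42 Spindlin1 and 92 C11orf84 peaks, Spindlin1 part 31.3%, 95% interval 23.6 to 39.9) and at 129 to 130 Mb (32 and 68), on chromosome 14 at 99 to 100 Mb (45 and 88) and on chromosome 19 at 54 to 55 Mb (62 and 116). Those richest in Spindlin1 were on chromosome 21 at 10 to 11 Mb (82 and 48, 63.1%, 54.2 to 71.4) and on chromosome 12 at 38 to 39 Mb (108 and 71, 60.3%, 52.8 to 67.6). The median background was at the floor in both lists in those 4 windows rich in C11orf84, but 2.07 and 2.18 times the floor in the window of chromosome 21 and 1.06 and 1.00 times in that of chromosome 12. Median summit depth in those 4 windows was 10 fragments for Spindlin1 and 10 or 11 for C11orf84. It was also 10 in both lists in the window of chromosome 12, but 14 and 15 in that of chromosome 21. These windows are the extremes of 777, so their intervals do not allow for that choice. By chromosome, the Spindlin1 part was lowest on chromosome X at 42.2% (39.9 to 44.5), followed by chromosome 19 at 42.8% (42.1 to 43.6), and highest on chromosome 8 at 49.5% (48.7 to 50.3). Median summit depth was 10 fragments in both lists on chromosomes X and 19, and 14 and 15 on chromosome 8. The Spindlin1 part may thus follow how deep the called peaks are, and a difference between the proteins was not tested.

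The short arm of chromosome 21 held deep peaks of both proteins next to each other. Spindlin1 had peaks at 9825376 to 9826596 (133 fragments, background 10.8 times the floor) and 9826661 to 9827520 (138 fragments, 23.4 times). C11orf84 had 1 peak across both, at 9825377 to 9827526 (148 fragments, 22.9 times). On chromosome 8 the background of peaks rose in neighbouring windows from 2.30 times the floor at 27 to 28 Mb through 2.68 at 28 to 29 Mb to 3.99 at 29 to 30 Mb in the Spindlin1 list. The C11orf84 list gave 2.33, 2.65 and 3.87 there. On chromosome 18 at 3 to 4 Mb it was 2.37 and 2.38 times, and on chromosome 2 at 92 to 93 Mb, beside the centromere, 5.71 and 5.45 times.

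Whether 1 Input library stood behind both lists was tested at 217 pairs of peaks whose summits fell on the same base and whose background came from the 10 kb window. The recovered number of Input reads was equal in 100% of the pairs, against 1.38% after shuffling the pairs. This is consistent with 1 Input library behind both lists, which could lend both lists some of the same false calls. Peaks at the floor, whose background was the same throughout a list, overlapped in 68.0% (67.7 to 68.3) of Spindlin1 and 53.4% (53.1 to 53.8) of C11orf84 cases, against at most 18.4% and 14.6% after local shifts. Standing at the floor is itself set by the Input, and coverage below the floor cannot be read. These shares therefore cannot separate the Input from binding.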
